A study of Danio rerio and Mus musculus with 16 samples.

How the data were processed

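The series holds 16 libraries from 2 species. The zebrafish part has 12 libraries from pools of genotyped larvae at 72 hours post fertilization, in 4 groups of 3: mutants of the rnpc3 lines clbnZM and clbns846 and a wild-type (WT) group for each line. These libraries were made from poly(A)-enriched RNA and read as 100 bp single ends. The mouse part has 4 libraries of dissected dorsal telencephalon at embryonic day 14, 2 from controls with 1 floxed and 1 wild-type Rnu11 allele and 2 from mutants with both alleles floxed, all carrying Emx1-Cre, a recombinase expressed in the progenitors of the dorsal telencephalon. The mouse libraries were made from stranded total RNA after depletion of ribosomal RNA.

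For the zebrafish the authors deposited, per line, a retention index (also called a mis-splicing index) for each intron and library as a fraction from 0 to 1. Per the submitters' notes, reads were aligned to GRCz11 with HISAT2 and intersected with bedtools. The index is relative to reads of the same intron in the same library and is not scaled between libraries. How the authors chose the introns, whether each is a minor (U12-type) intron, the reads behind each value, the tool versions and whether start positions count from the first base are not given in the sources used here. The depth per intron is therefore unknown, no interval is given for an index, and a value of 0 may also stand for an intron without reads. For the mouse the authors deposited raw counts per gene, made with HISAT2 and featureCounts on mm10. The annotation, the strand setting and the handling of reads that map more than once are not given in the sources used here.

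Every intron had a value in each library of its table, so none was left out. Each line was compared with its own WT libraries by limma 3.58.1 (robust empirical Bayes, two-sided) on the arcsine of the square root of the index, in R 4.3.3, and Benjamini-Hochberg adjusted p values were compared with a threshold of 0.05. The library medians over introns were compared by an exact two-sided permutation test, in which 3 against 3 libraries cannot give a p below 0.1. Introns present in both tables were tested for a different change in the lines by the interaction term of a limma fit of all 12 libraries. Host genes were grouped by symbol into 12 lists, and the introns called higher in each list were counted against all other introns of the table by a two-sided Fisher exact test, adjusted over the 10 lists per line that held at least 3 introns.

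Mouse counts were filtered with filterByExpr, scaled with TMM factors and tested with the quasi-likelihood F-test of edgeR 4.0.16, with the same threshold of 0.05. CPM values printed here are counts scaled to the library total and given per 1e+06 counts, while log2 fold changes also carry the TMM factors. Standard errors of log2 fold changes were derived from the F statistic. Of the 55471 identifiers in each count table, 55144 matched GENCODE M21, which gave symbols, positions and exon lengths, and 327 did not. The 30 mouse gene lists were tested with camera on log2 CPM (prior count 2) with its preset correlation of 0.01, two-sided and adjusted over the lists. Camera with a correlation estimated from the data and fry were run beside it. With an estimated correlation, camera tests on the residual degrees of freedom, which are few with 2 libraries per group. A list can then hardly pass after adjustment, so its adjusted p values are no evidence against a list. For each list, the members past the threshold over all genes were counted, and also those past it when adjusted over the list alone. Total counts per mouse library ran from 13227067 to 43308211. Intervals for shares of counts are exact 95% binomial intervals and cover counting error only, since reads without molecular identifiers are not independent molecules.

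The groups, tests, gene lists, alternative settings and the rule for named genes were fixed before the data were examined. In the mouse the rule took the measured minor spliceosome components; the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 CPM and both mutants beyond both controls, leaving out predicted symbols; and up to 4 members per list with the smallest adjusted p, or where none passed the 2 most abundant. In the zebrafish it took each intron of rnpc3, the 8 largest rises and 4 largest falls per line among introns past the threshold whose 3 mutant libraries lay beyond the 3 WT libraries, and up to 2 introns per host gene list. Some genes that the rule takes are not reported here. Members named beyond this rule were chosen after their values were seen, and the text says where.

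Alternatives for the mouse were other scaling factors, other filters on low counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out abundant genes, a fold threshold and leaving out each library. Alternatives for the zebrafish were an untransformed and a logit scale, a minimum index, a minimum change, a block, an ordinary variance prior and leaving out each library. Chosen after seeing the data were the removal of an even background from the mouse counts, a limit on that background, a minimum mean of 5 CPM, robust dispersions, and the host gene list tests under each alternative fit. The background was the count per exonic kilobase over 1479 olfactory, vomeronasal and trace amine receptor genes in each library. The planned search for mouse genes with U12-type introns needs genome sequence and was not run.

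The tests were tried on simulated data. In simulated mouse counts of 21082 genes, 100 were changed 2-fold and 100 changed 4-fold, as many up as down. With per-gene dispersions, edgeR recovered 22% of genes changed 2-fold and 81% of those changed 4-fold, and 22 of its 125 calls (17.6%) were false. With dispersions on the fitted trend it recovered 45% and 89%, and 6 of 140 calls (4.29%) were false. In the data 4576 genes passed, a far larger share than was simulated, so these rates do not carry over to the real calls. In simulated zebrafish tables of 510 and 484 introns, limma recovered 73% and 80% of 100 introns shifted by 0.5 on the arcsine scale, with 5 and 4 false calls. Replicates were checked for copies: counts of mouse replicates differed by more than counting error (chi-square per degree of freedom 41.8 in controls and 25.0 in mutants), and no zebrafish pair within a group shared more than 3.13% of its values between 0 and 1. Replicate numbers did not pair the libraries: the correlation of replicate differences was -0.00526 in the mouse and ran from -0.0637 to 0.127 over replicate numbers and lines in the zebrafish, so no block was used in the main tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.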

Results

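Minor introns are a small class of introns removed by their own spliceosome, in which the U11 and U12 RNAs recognise the intron and rnpc3 encodes a protein that bridges them. A zebrafish and a mouse model with a damaged minor spliceosome were sequenced. In zebrafish larvae, retention was measured for 510 introns in 475 genes in the line clbnZM and for 484 introns in 446 genes in the line clbns846, each with 3 mutant and 3 WT libraries of pooled larvae. Values are given as an index, a fraction from 0 (spliced) to 1 (retained), with an unknown number of reads behind each, so that an index of exactly 0 or 1 may rest on few reads. In mouse dorsal telencephalon, gene counts were measured in 2 controls and 2 Rnu11 mutants. The total counts were 43308211 and 26253275 in the controls and 13227067 and 22719068 in the mutants.

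The first comparison asked which introns were retained more in clbnZM mutants than in their WT larvae. Introns of genes with unrelated roles went from an index of 0 to 1. The index was 0 in all 3 WT libraries and 1 in all 3 mutant libraries for rapgef1a, which encodes an exchange factor for Rap GTPases (chromosome 8 of GRCz11, 11789591 to 11789684 as filed). The same held for atg9a, which encodes a membrane protein of autophagy (chromosome 6, 11252737 to 11252835), and for vps11, which encodes a subunit of endosomal tethering complexes (chromosome 10, 29767817 to 29768361). It held also for the sodium channel gene scn1lab (chromosome 6, 10301108 to 10301688). Single introns of cep170aa, zcchc8 and C3H17orf75 changed in the same way, which made 7 such introns (limma adjusted p = 2.8e-09 for each). With an SD of 0 in both groups, this p is set by the variance prior of limma and measures no spread between replicates. The number of reads behind these values is unknown. In an intron of paxip1, which encodes a protein of the DNA damage response, the index rose from 0.0899 ± 0.0649 to 0.913 ± 0.0442 (SD, n = 3).

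Of the 510 introns, 210 in 207 genes were higher in clbnZM mutants and 1 was lower, an intron of epyc, a gene for a cartilage proteoglycan, which went from 0.266 ± 0.0724 to 0.111 ± 0.0309 (SD, n = 3, limma adjusted p = 0.0408). The call for epyc was lost without any 1 of 5 libraries (WT 1, WT 3 or any mutant), with adjusted p from 0.0692 to 0.131. Among the higher introns the median change was 0.291. All 3 mutants lay above all 3 WT libraries in 241 introns and below them in 8, where chance gives at most 10% of introns over both directions together. The library medians were 0.0291 ± 0.0255 in WT and 0.360 ± 0.0168 in mutants (SD, n = 3), and the exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. WT library 3 stood apart, with 363 of its 510 introns at 0 against 141 and 138 in the other WT libraries. Without it 186 introns passed, 184 of them higher, and 166 of the 186 were among the original calls.

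In clbnZM, 3 host gene lists passed narrowly. For nuclear transport, 8 of 9 introns of nuclear import and export genes were higher against 40.3% of other introns (8 when adjusted over the list alone, Fisher exact test, adjusted p = 0.0441). They include kpnb3 and ipo9, genes for import receptors, whose introns rose from 0 to 0.346 ± 0.0122 and 0.530 ± 0.0319 (SD, n = 3). Vesicle trafficking followed with 11 of 15 introns (11 adjusted over the list alone, Fisher exact adjusted p = 0.0487), among them trappc10, a gene for a subunit of a Golgi tethering complex, at 0 in WT and 0.282 ± 0.0174 in mutants. Proteasome and ubiquitin genes had 9 of 11 higher (9 adjusted over the list alone, Fisher exact adjusted p = 0.0481), with usp10, for a deubiquitinase, at 0.404 ± 0.00834 and derl3, for a protein of endoplasmic reticulum degradation, at 0.364 ± 0.0336, both from 0. These calls were close to the threshold: all 3 were lost without mutant 2 (adjusted p = 0.0665 for each), without WT 1 (0.0605 to 0.0649) and without WT 2 (0.131 to 0.273), and the proteasome call also without WT 3 (0.127). All 3 were also lost with a replicate block (0.276 to 0.450) and on the untransformed index (0.171 to 0.194). Without WT 3, MAP kinases and RAF passed with 6 of 7 introns (Fisher exact adjusted p = 0.0340).

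The other lists of clbnZM did not pass. MAP kinases and RAF had 4 of 7 introns higher (5 adjusted over the list alone, Fisher exact adjusted p = 0.567), including mapk3, a gene of growth factor signalling, from 0 to 0.126 ± 0.0205 (SD, n = 3). Exosome and integrator genes had 4 of 6 (5 alone, adjusted p = 0.392), with exosc9 from 0.00337 ± 0.00583 to 0.124 ± 0.0162. Splicing factors and snRNP proteins had 1 of 4 (1 alone, adjusted p = 0.647), an intron of snrpe that rose from 0.00225 ± 0.00389 to 0.0296 ± 0.00319, a call lost without mutant 1, mutant 2 or WT 3 (limma adjusted p = 0.0563, 0.0530 and 0.0508). DNA replication and repair had 5 of 7 (5 alone, adjusted p = 0.325), but its best introns lie in polr1e, at 0.293 ± 0.0753, and polr2eb, at 0.199 ± 0.0286, whose products are RNA polymerase subunits. Transport ATPases and solute carriers had 7 of 14 (7 alone, adjusted p = 0.647), cilia and microtubule motors 4 of 7 (4 alone, adjusted p = 0.567), and transcription and chromatin 4 of 5 (4 alone, adjusted p = 0.330). With 2 introns each, E2F factors (1 higher, in e2f4, from 0.00901 ± 0.0156 to 0.601 ± 0.0474) and sodium and calcium channels (1 higher, in scn1lab) were not tested.

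The second line, clbns846, put the same question to another rnpc3 allele, and its table includes an intron of rnpc3 itself (chromosome 24, 28963218 to 28963401, plus strand). Retention of that intron rose from 0.00629 ± 0.0109 in WT to 0.742 ± 0.0930 in mutants (SD, n = 3, limma adjusted p = 0.00136). This intron lies in the mutated gene, and an effect of the allele on its own transcript was not tested. Introns of rapgef1a and atg9a again stood at 0 in all 3 WT and at 1 in all 3 mutant libraries (limma adjusted p = 1.7e-12). So did those of crtc1a, which encodes a coactivator of CREB, and of vps52, which encodes a subunit of a Golgi tethering complex, with the same adjusted p. Here too the SD was 0 in both groups, so this p is set by the variance prior. Further large rises were found in mtg1, for a mitochondrial GTPase (0.0952 ± 0.0825 to 1), and in rfx7a, for a transcription factor (0.0556 ± 0.0962 to 0.952 ± 0.0825). Others were in plcd3b, for a phospholipase (0.0196 ± 0.0340 to 0.933 ± 0.115), and in drc3, for a dynein regulator of motile cilia (0.0847 ± 0.0750 to 0.917 ± 0.144).

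In clbns846, 204 of 484 introns in 196 genes were higher and 8 were lower, with a median change of 0.307 among the higher. The 4 largest falls were in slitrk4, for a synaptic adhesion protein (0.761 ± 0.0674 to 0.463 ± 0.0730), in BX470246.1 (0.981 ± 0.0321 to 0.847 ± 0.0533) and in the genes of the RNA-binding proteins qkia (0.0994 ± 0.00990 to 0.0388 ± 0.0199) and rbm39a (0.121 ± 0.0216 to 0.0614 ± 0.0104; SD, n = 3). None of the 4 falls was called in every fit that left out 1 library. The call for slitrk4 was lost without mutant 2 (adjusted p = 0.0561) or WT 1 (0.0546). That for rbm39a was lost without mutant 1, mutant 3, WT 1 or WT 2 (0.0504 to 0.0749), that for qkia without mutant 3 or any WT library (0.0808 to 0.120), and that for BX470246.1 without any mutant, WT 1 or WT 2 (0.0821 to 0.132). Mutants lay beyond WT upwards in 231 introns and downwards in 21, where chance gives at most 10% over both directions together. Library medians were 0.0498 ± 0.00601 in WT and 0.344 ± 0.0102 in mutants (SD, n = 3), with an exact two-sided permutation p = 0.1, again the smallest possible.

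Nuclear transport and vesicle trafficking also passed in clbns846, and proteasome and ubiquitin did not. All 8 introns of nuclear import and export genes were higher against 41.2% of other introns (8 adjusted over the list alone, Fisher exact adjusted p = 0.00665). Among them kpnb3 rose from 0.00556 ± 0.00481 to 0.204 ± 0.0301 and the exportin gene xpo7 from 0 to 0.329 ± 0.0486 (SD, n = 3). Vesicle trafficking had 12 of 14 (12 alone, Fisher exact adjusted p = 0.00665), with trappc1 from 0.0175 ± 0.0104 to 0.340 ± 0.0294. Both calls were lost without any 1 of the 3 mutants, WT 1 or WT 2 (adjusted p from 0.0557 to 0.187), and vesicle trafficking also without WT 3 (0.116). With a replicate block both were lost (0.0633 for each). The remaining lists did not pass. MAP kinases and RAF had 6 of 7 (7 alone, adjusted p = 0.151), with mapk14a from 0.00901 ± 0.0156 to 0.208 ± 0.0532. Proteasome and ubiquitin had 8 of 13 (8 alone, adjusted p = 0.276) and exosome and integrator 4 of 6 (5 alone, adjusted p = 0.307). DNA replication and repair had 4 of 6 (5 alone, adjusted p = 0.307), with the repair enzyme gene parp1 from 0.00312 ± 0.00540 to 0.137 ± 0.0165. Cilia and microtubule motors had 5 of 6 (5 alone, adjusted p = 0.218), and transport ATPases and solute carriers 8 of 12 (8 alone, adjusted p = 0.271). Transcription and chromatin had 3 of 4 (3 alone, adjusted p = 0.350), with the mRNA export gene thoc2 from 0.0997 ± 0.0311 to 0.527 ± 0.0111, and splicing factors 3 of 5 (3 alone, adjusted p = 0.654). E2F factors (1 of 2 higher) and sodium and calcium channels (0 of 2) were not tested.

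**Figure D1:**
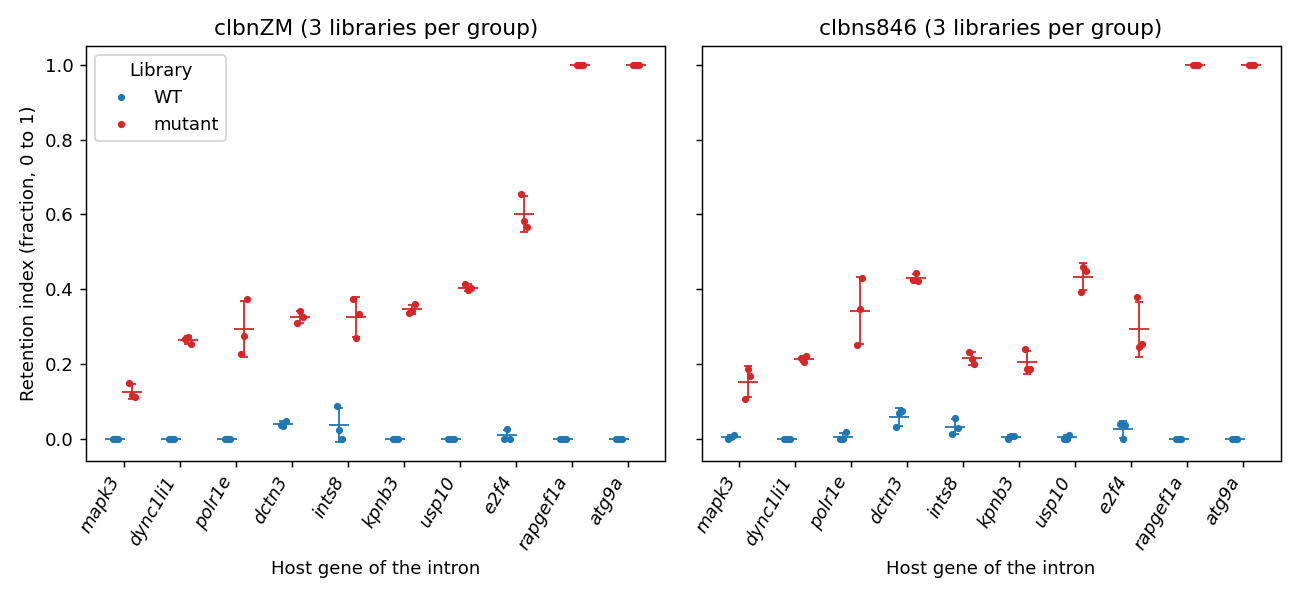
Retention index (fraction, 0 to 1) of introns in 10 host genes in clbnZM (left) and clbns846 (right), one point per library (blue WT, red mutant), with the mean and SD of 3 libraries per group. The introns are those that the rule named in both lines, all past the threshold. That the mutant points lie above the WT points in each gene shown therefore follows largely from this choice. The values run from mapk3 (mean 0.126 in clbnZM mutants) to rapgef1a and atg9a, at 1 in all 6 mutant libraries.

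The lines were then set side by side on the 407 introns found in both tables. The introns that rose were largely shared: 172 were higher in clbnZM, 183 in clbns846 and 155 in both, where 77.3 would be expected of independent lists (Fisher exact p = 1.2e-61). That p treats introns as independent. In the full tables, 35 introns of clbnZM and 70 of clbns846 stood at 1 in every library and could not rise. Those present in both tables can enlarge the overlap, and such introns also count among the other introns in the host gene list tests. The 155 lie in 153 genes, with median changes of 0.321 in clbnZM and 0.308 in clbns846, and include dctn3 and dync1li1, for parts of the dynein motor and its activator, ints8, for an integrator subunit, usp10 and e2f4. The index of usp10 rose by 0.404 and 0.430, dctn3 by 0.286 and 0.371, and e2f4 by 0.592 and 0.267 in clbnZM and clbns846. Across introns, which are not independent replicates, the changes correlated with Pearson r = 0.698 and Spearman rho = 0.659. No intron was higher in one line and lower in the other. The limma interaction called 0 introns, with 21 at an unadjusted p under 0.05, so a difference between the lines was not shown for any intron, although on the untransformed scale 8 passed. Without clbnZM WT 1, WT 2 or WT 3 or clbns846 mutant 3, 1 intron passed, and without clbns846 WT 1, 2 did. The call for ints8 in clbnZM was lost without mutant 1, mutant 3 or WT 2 (limma adjusted p = 0.0626, 0.0624 and 0.0581).

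**Figure D2:**
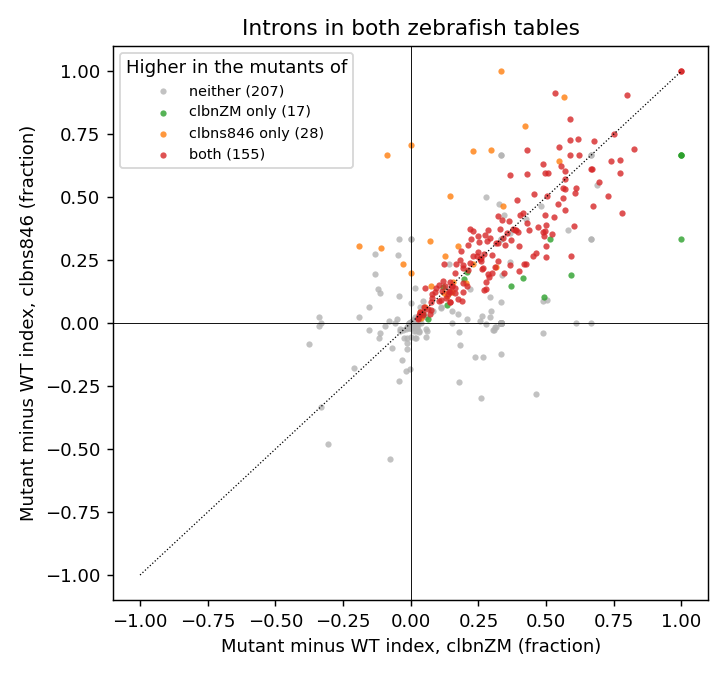
Change of the retention index (mutant mean minus WT mean, fraction) in clbnZM (horizontal) against clbns846 (vertical), one point per intron in both tables, coloured by the line in which it was higher, with a dotted line of equal change. The 155 introns higher in both lines have positive changes on both axes, and 207 were higher in neither.

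The mouse comparison asked how loss of U11 in the dorsal telencephalon changes gene expression at embryonic day 14. Targets of p53 were among the largest rises. Pmaip1, which encodes a pro-apoptotic protein (chromosome 18 of mm10, 66458533 to 66465565), went from 0.480 ± 0.301 to 13.7 ± 5.05 CPM (SD, n = 2). Eda2r, for a receptor of the tumour necrosis factor family (chromosome X, 97333840 to 97377216), went from 6.19 ± 0.722 to 68.1 ± 20.2 CPM. Genes of phagocytes rose with them, among them Spp1 (log2 fold change 4.51 ± 0.28, SE), Cd36 (3.62 ± 0.51), the complement receptor gene C3ar1 (3.47 ± 0.22) and Gpnmb (7.46 ± 1.17), and so did Ano3, for a membrane protein of the anoctamin family (4.41 ± 0.39). The largest falls were in Amd2, for an enzyme of polyamine synthesis, from 84.7 ± 11.7 to 8.67 ± 1.25 CPM (chromosome 10, 35708675 to 35711892), and in Snora78, for a small nucleolar RNA (-1.81 ± 0.32). Among the 8 were also 6 histone genes, Hist1h4j (-2.17 ± 0.36), Hist1h2ap (-2.03 ± 0.36), Hist1h2an (-1.93 ± 0.13), Hist1h2ah (-1.92 ± 0.16), Hist1h2ai (-1.83 ± 0.32) and Hist1h2af (-1.80 ± 0.20). With robust dispersions, chosen after seeing the data, the calls of Gpnmb, Cd36, Snora78, Hist1h2ai, Hist1h2ap and Hist1h4j were lost (adjusted p = 0.141, 0.0922, 0.0562, 0.125, 0.151 and 0.123), and that of Hist1h4j also without mutant 1 (0.0775).

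Of 21082 genes tested, 3142 were higher and 1434 lower in mutants (edgeR). The first principal component held 74.8% of the variance and parted mutants from controls. The counts depend on single libraries: 1260 genes passed without mutant 1, 3007 without mutant 2, 3345 without control 2 and 4131 without control 1. The number called per list varied with them, and is given below as a range over the 4 fits without 1 library where it changed by more than 1.5 times. The balance of rises and falls depends on the settings: DESeq2 gave 1999 up and 2213 down, and genes with a mean of at least 5 CPM alone gave 1072 up and 1294 down. The rises were concentrated in genes with few counts. Under a mean of 1 CPM, 1022 genes rose and 13 fell, and from 1 to 5 CPM, 1020 rose and 54 fell. From 5 to 20 CPM, 723 rose and 315 fell. From 20 to 100 CPM, 336 rose and 802 fell, and above 100 CPM, 41 rose and 250 fell. The median log2 fold change fell with abundance: 0.61 under 1 CPM, 0.27 from 1 to 5 CPM, -0.16 from 20 to 100 CPM and -0.22 above 100 CPM. Camera compared each list with all other genes, so lists of abundant genes may lean down and lists of low-count genes up. The mutant libraries also held 40938 and 41317 genes with a count, against 31807 and 30094 in the deeper controls, and receptor genes of the nose summed to 376.9 and 225.4 CPM against 15.5 and 18.0. After an even background of that size was taken off, 2238 genes rose and 888 fell, and 3105 of these 3126 had been called before. Xist, which silences an X chromosome in females, passed with a log2 fold change of 11.16 ± 2.97 (SE) through mutant 2 alone: it had 869.1 CPM there and 0.162, 0.229 and 0.605 CPM in the other libraries, and without mutant 2 its adjusted p was 0.211. The Y-linked Ddx3y had 0 counts in mutant 2 and 107.9, 107.4 and 111.4 CPM elsewhere, so the libraries differ in sex within the mutant group.

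Rnu11, the gene of U11 (chromosome 4 of mm10, 132270080 to 132270213, minus strand), had 0 counts in each of the 4 libraries, so its loss could not be read from the table. A count of 0 allows up to 0.0693 and 0.114 CPM in the controls and 0.227 and 0.132 CPM in the mutants for reads assigned to Rnu11. On the other strand, Gm28872 spans the whole of Rnu11 and had 16 counts in each control and 5 and 2 in the mutants. With the strand setting not given, reads of the locus may have been dropped or assigned elsewhere. The limits therefore do not bound the amount of U11 RNA. Rnu12, which encodes the U12 RNA, rose from 41.8 to 87.1 CPM (log2 fold change 1.00 ± 0.23, SE, n = 2, edgeR adjusted p = 0.0257), but not past the threshold without control 2 (0.73, adjusted p = 0.0533) or mutant 2 (0.73, adjusted p = 0.0907). The 11 protein genes measured did not pass. Snrnp25, at -0.48 ± 0.15 (adjusted p = 0.0592), came closest and passed with robust dispersions (0.0480), and Scnm1, at -0.42 (adjusted p = 0.122), passed without control 1 (0.0278). With no filter on low counts Snrnp25 (0.0105), Scnm1 (0.0139) and Pdcd7 (0.0390) passed downwards. Rnpc3 stood at 0.05 ± 0.12. Ccdc84, Snrnp35, Zcrb1, Zmat5, Zrsr2, Snrnp48, Pdcd7 and Txnl4b lay from -0.38 to -0.10, with the sign of Ccdc84 positive under upper quartile factors (0.01) and that of Rnpc3 negative under DESeq2 (-0.04). Without control 2 these signs changed as well (0.04 for Ccdc84 and -0.03 for Rnpc3). All tested genes at a mean of 20 to 100 CPM had a median of -0.16, and no list was compared with genes of like abundance. As a list the 12 components were lower than other genes (median -0.22, 1 up and 0 down, the same when adjusted over the list alone, adjusted p = 0.0436; adjusted p = 0.438 with an estimated correlation). The call was also lost without control 1 (adjusted p = 0.0575), control 2 (0.0540) or mutant 1 (0.0937), with a replicate block (0.0623) and after background removal (0.106). Without 1 library, 0 to 1 were up and 0 to 1 down.

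Stress pathways differed in how far they moved. Of 29 measured p53 target genes, 18 rose and 1 fell (20 and 1 adjusted over the list alone), with a median log2 fold change of 1.11 (adjusted p = 1.2e-06; adjusted p = 0.373 with an estimated correlation). Beside Pmaip1 and Eda2r, the cyclin gene Ccng1 rose by 2.18 ± 0.16 and Polk, for a DNA polymerase that bypasses lesions, by 1.35 ± 0.11 (SE). Btg2 fell by 0.47, a call lost without any 1 library (adjusted p from 0.0639 to 0.126). Mdm2, the p53 inhibitor, chosen after its value was seen, stood at 0.13 ± 0.12 (adjusted p = 0.438). Interferon response genes had 13 of 19 up (14 alone, median 1.40, adjusted p = 1.6e-06; adjusted p = 0.349 with an estimated correlation), with Rsad2 at 3.35 ± 0.43 and Oasl2 at 2.59 ± 0.33, both below 4 CPM in every library. The integrated stress response did not pass as a list (3 up, 5 down of 23; 4 and 7 alone; test direction down, adjusted p = 0.360), and its median of -0.19 and mean of 0.09 differed in sign. The cystine transporter gene Slc7a11 rose by 1.32 ± 0.16 while Shmt2, for a mitochondrial enzyme of serine metabolism, stood at -0.93 ± 0.15. Unfolded protein response and heat shock genes did not pass either (3 up, 2 down of 25; 3 and 2 alone; median 0.05, mean 0.26, test direction down, adjusted p = 0.895), with the chaperone gene Hspa1a up by 4.02 ± 0.48 from 0.0652 to 1.28 CPM. Antioxidant NRF2 targets had 5 up and 2 down of 17 (5 and 3 alone, median 0.21, adjusted p = 0.390), led by Hmox1, for heme oxygenase, at 2.00 ± 0.20. Markers of microglia and macrophages rose in the same libraries (median 2.30), and a change in cell content was not separated from the changes in these lists. Without 1 library, 2 to 12 interferon response genes were up. The integrated stress response had 1 to 3 up and 1 to 3 down, unfolded protein response and heat shock 1 to 3 up and 0 to 1 down, and NRF2 targets 2 to 5 up and 0 to 1 down.

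Lists of progenitor and cell cycle genes were lower than other genes with the preset correlation, though many members were not called. In intermediate progenitors, the dividing cells that give rise to cortical neurons, 11 of 15 markers fell (15 adjusted over the list alone, median -0.78, adjusted p = 4.2e-08; adjusted p = 0.349 with an estimated correlation). Eomes went from 115.9 ± 13.8 to 52.9 ± 3.26 CPM (SD, n = 2), and the neurogenic factor gene Neurog2 stood at -1.15 ± 0.12 (SE). Radial glia, the stem cells of the cortex, had 10 markers down and 1 up of 24 (12 and 1 alone, median -0.43, adjusted p = 3.7e-05; adjusted p = 0.349 with an estimated correlation). The Notch effector gene Hes5 was at -1.60 ± 0.15, Id4 at -1.44 ± 0.13 and Aldoc at -1.41 ± 0.14, and Ednrb was the member that rose (0.73, chosen after its value was seen). S phase genes had 18 of 30 down (27 alone, median -0.57, adjusted p = 2.4e-11; adjusted p = 0.349 with an estimated correlation), such as Rrm2, for a subunit of ribonucleotide reductase (-0.98 ± 0.11), and Chaf1b, for a histone chaperone (-0.96 ± 0.13). G2 and M phase genes had 12 of 30 down (19 alone, median -0.46, adjusted p = 2.1e-07; adjusted p = 0.373 with an estimated correlation), with the centromere histone gene Cenpa at -0.81 ± 0.12 and Cdca8 at -0.79 ± 0.13. E2F factors, a gene family known for U12-type introns, had 2 of 6 down (2 alone, median -0.35, adjusted p = 0.0302; adjusted p = 0.373 with an estimated correlation; adjusted p = 0.103 without mutant 2). The call of E2f3 was lost without any 1 library (adjusted p from 0.0651 to 0.114), and that of E2f5 without control 1 (0.0555) or mutant 1 (0.0986). Without 1 library, 7 to 11 intermediate progenitor markers, 6 to 9 of radial glia, 11 to 21 S phase genes, 3 to 15 G2 and M phase genes and 0 to 1 E2F factors were down.

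Neuronal markers did not move as 1 group. Among 22 genes of glutamatergic cortical neurons, 3 rose and 3 fell (3 and 5 alone, median -0.29, adjusted p = 0.0322; adjusted p = 0.438 with an estimated correlation), and the call was lost without mutant 2 (adjusted p = 0.114) and after background removal (0.0893). Unc5d, for a netrin receptor, was at -1.02 ± 0.13 (SE) and Ldb2, for a transcriptional cofactor, at 0.86 ± 0.15 (adjusted p = 0.0555 without mutant 1). Pan-neuronal genes had 2 up and 2 down of 23 (2 and 0 alone, median 0.07, adjusted p = 0.853), with the synaptotagmin gene Syt1 at 0.81 ± 0.16, lost without mutant 1 (0.63, adjusted p = 0.0822). Markers of Cajal-Retzius cells, early neurons of the cortical surface that arise in part outside the Emx1 lineage, had 6 of 11 up (10 alone, median 0.90, adjusted p = 0.000991; adjusted p = 0.438 with an estimated correlation). Ndnf was at 1.53 ± 0.24 and Ebf3 at 1.26 ± 0.21. GABAergic interneuron genes, of cells born in the ventral telencephalon, had 7 of 17 up and 0 down (14 and 1 alone, median 0.84, adjusted p = 0.000282; adjusted p = 0.373 with an estimated correlation). Maf was at 2.06 ± 0.19 and Erbb4 at 1.27 ± 0.16. Genes of the striatum and ventral telencephalon had 5 of 12 up (5 alone, median 1.13, adjusted p = 0.00503; adjusted p = 0.349 with an estimated correlation), with Rarb at 1.70 ± 0.25 and Ebf1 at 1.31 ± 0.18. Without 1 library, 3 to 8 Cajal-Retzius markers, 2 to 7 interneuron genes and 2 to 6 genes of the striatum and ventral telencephalon were up. Glutamatergic genes had 0 to 3 up and 2 to 3 down, and pan-neuronal genes 0 to 5 up and 0 down.

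Markers of microglia, vessels, mesenchyme and choroid plexus rose. All 20 genes of microglia and macrophages were up (20 alone, median 2.30, adjusted p = 2.4e-11; adjusted p = 0.373 with an estimated correlation). The summed CPM of the list went from 125.3 and 112.1 in controls to 716.6 and 439.8 in mutants. Ptprc, for a leukocyte phosphatase, rose by 2.73 ± 0.21, Tyrobp, for a microglial adaptor, by 2.66 ± 0.19 and C1qb, for a complement subunit, by 2.31 ± 0.17 (SE, n = 2). Endothelium had 14 of 18 up (17 alone, median 1.04, adjusted p = 2.2e-07; adjusted p = 0.349 with an estimated correlation), with the cadherin gene Cdh5 at 1.90 ± 0.12. Pericytes and smooth muscle had 8 of 10 up (8 alone, median 1.25, adjusted p = 0.000144; adjusted p = 0.349 with an estimated correlation), with Rgs5 at 1.24 ± 0.12. Meninges and mesenchyme had 13 of 16 up (15 alone, median 1.44, adjusted p = 4.2e-08; adjusted p = 0.349 with an estimated correlation), with the collagen genes Col1a1 at 2.09 ± 0.15 and Col1a2 at 1.82 ± 0.12. Choroid plexus and cortical hem had 12 of 16 up (16 alone, median 1.88, adjusted p = 1.7e-06; adjusted p = 0.373 with an estimated correlation), with the hem genes Rspo2 at 1.87 ± 0.20 and Lmx1a at 1.81 ± 0.24. Ttr, the main secreted product of the plexus, chosen after its value was seen, had 469.2 and 38.9 CPM in controls and 2295 and 1512 CPM in mutants and did not pass (adjusted p = 0.0885). Red blood cell genes had 3 of 13 up (5 alone, median 0.80, adjusted p = 0.00760; adjusted p = 0.559 with an estimated correlation), with Hba-x, an embryonic globin gene, from 22.1 ± 0.722 to 63.6 ± 25.8 CPM (SD, n = 2). The list call was lost without control 2 (adjusted p = 0.0866) or mutant 2 (0.114), and that of Hba-x with robust dispersions (0.146). Without 1 library, 8 to 14 genes of endothelium, 5 to 16 of choroid plexus and hem and 1 to 7 of red blood cells were up, the lowest for endothelium and plexus without mutant 1.

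Lists of neighbouring tissue and of other processes varied. Diencephalon genes had 1 of 5 up (3 alone, median 1.45, adjusted p = 0.0703), namely Foxd1 at 1.80 ± 0.24, and passed without control 1 (adjusted p = 0.0112), control 2 (0.0405) or mutant 2 (0.0433). Oligodendrocyte lineage genes had 2 of 4 up and 0 down (2 and 1 alone, median 0.65, adjusted p = 0.531), with Pdgfra, also a gene of meningeal fibroblasts, at 1.90 ± 0.14. Immediate early genes had 3 up and 2 down of 14 (5 and 2 alone, median 0.42, adjusted p = 0.147), with Fos at 2.44 ± 0.34 from 0.352 CPM in controls. Genes of cholesterol synthesis fell in 14 of 16 (15 alone, median -0.79, adjusted p = 1.6e-07; adjusted p = 0.349 with an estimated correlation), including the synthase gene Hmgcs1 (-0.79 ± 0.13). Glycolysis and hypoxia genes had 2 up and 4 down of 18 (2 and 6 alone, median -0.05, mean 0.02, adjusted p = 0.201), with the hexokinase gene Hk2 at -0.79 ± 0.13, and passed downwards without control 1 (adjusted p = 0.0267). Mitochondrial mRNAs had 4 of 13 up (8 alone, median 0.58, adjusted p = 0.00341; adjusted p = 0.559 with an estimated correlation), with mt-Nd1 at 0.87 ± 0.22. The list call was lost without control 2 (adjusted p = 0.143) or mutant 2 (0.0515), and that of mt-Nd1 also without mutant 1 (0.0835). Without 1 library, 4 to 12 cholesterol genes were down and 0 to 11 mitochondrial mRNAs up. Diencephalon had 1 to 4 up and the oligodendrocyte lineage 1 to 3. Immediate early genes had 1 to 3 up and 0 to 1 down, and glycolysis and hypoxia 0 to 1 up and 1 to 4 down.

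The last lists were 2 more gene families known for U12-type introns. Sodium and calcium channels had 5 of 15 up and 0 down (6 and 0 alone, median 0.33, adjusted p = 0.00760; adjusted p = 0.373 with an estimated correlation; adjusted p = 0.0575 without control 1), with Scn2a at 0.92 ± 0.12 (SE). Without mutant 1 only 1 was called, and Scn9a, Cacna1g and Scn3a were lost (adjusted p = 0.0809, 0.0979 and 0.0568). Scn3a was lost without any 1 library (adjusted p from 0.0563 to 0.160). MAP kinases and RAF had 1 up and 3 down of 12 (2 and 4 alone, median -0.04, adjusted p = 0.233). Mapk11 was at -1.11 ± 0.14 and Mapk14 at -0.75 ± 0.12, both kinases of stress signalling, while Mapk8 was at 0.52 ± 0.14. The call for Mapk14 was lost without mutant 1 (-0.71, adjusted p = 0.0553), and that for Mapk8 without any 1 of the 4 libraries (adjusted p from 0.0747 to 0.294), which left 0 up and 2 to 3 down. In all, 21 of 30 lists passed camera with the preset correlation. With an estimated correlation 0 passed (lowest adjusted p = 0.349, 1 list at an unadjusted p under 0.05), and fry, which does not compare a list with other genes, passed 14. The estimated form has few residual degrees of freedom here and could hardly pass any list. For radial glia the estimated correlation was -0.0058, below the preset 0.01, and the unadjusted camera p still went from 1.3e-05 to 0.0403. The 0 therefore does not decide whether the lists moved.

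**Figure D3:**
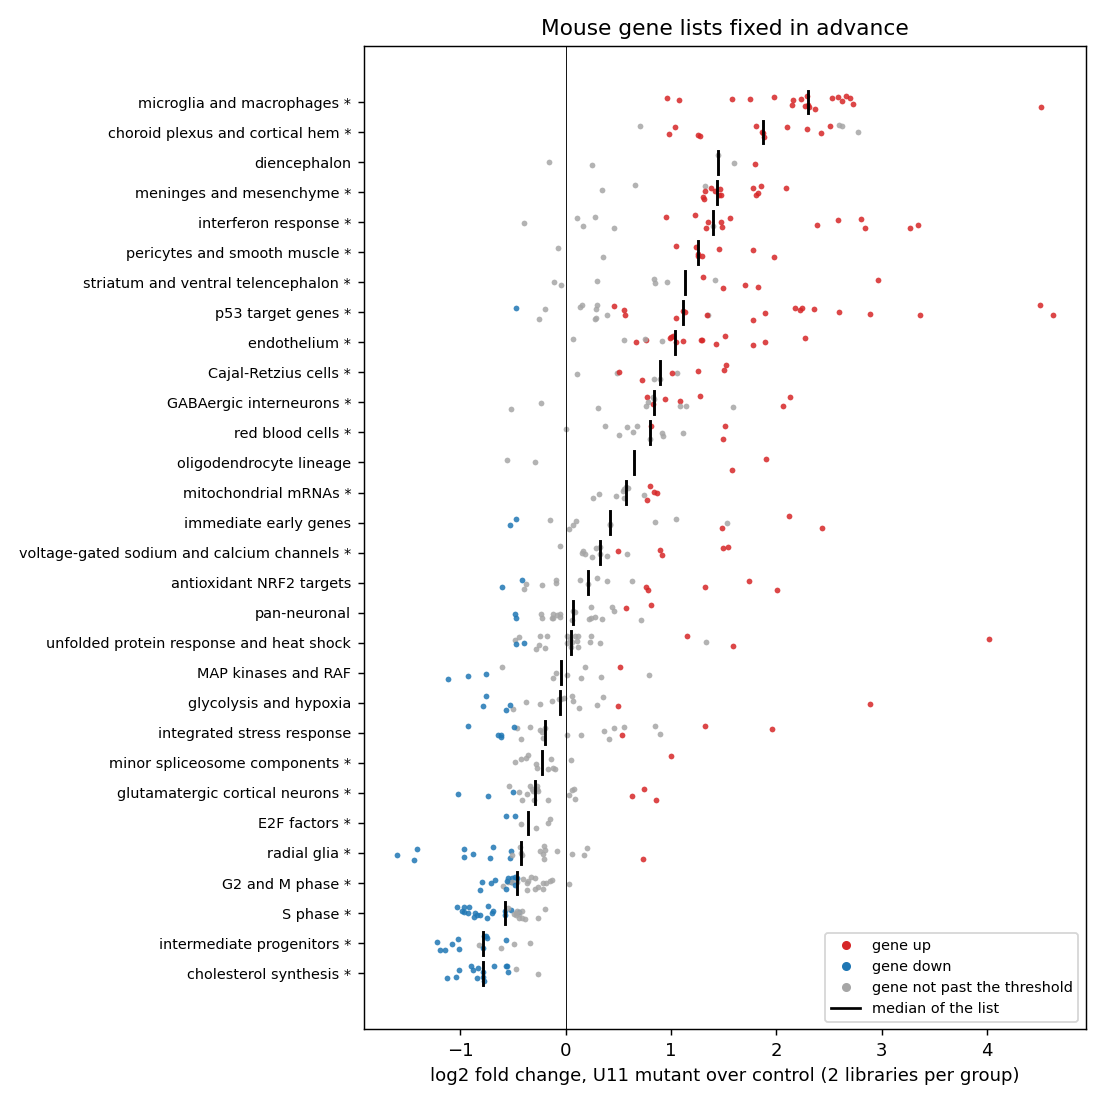
Log2 fold change (mutant over control, 2 libraries per group) of the measured members of 30 gene lists, one point per gene (red up, blue down, grey not past the threshold), with a black bar at the median of each list and an asterisk at the 21 lists past the threshold with the preset correlation. Microglia and macrophages have the highest median (2.30) and cholesterol synthesis the lowest (-0.79).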

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

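The test on library size and the count of rises kept after background removal were chosen after the values they use were seen, while the test on X-linked genes was set before. Olfactory, vomeronasal and trace amine receptor genes, most of which had too few counts to be tested, gave a signal in the mouse mutants far above the controls. Their 1479 genes summed to 376.9 CPM in mutant 1 (exact 95% interval 366.5 to 387.5) and 225.4 CPM in mutant 2 (219.2 to 231.6), against 15.5 CPM (14.3 to 16.7) in control 1 and 18.0 CPM (16.4 to 19.7) in control 2. A count was found for 1265 and 1274 of them in the mutants and for 218 and 194 in the controls. Spread evenly over all exons, this density amounts to 0.899% and 0.537% of the counts in the mutants and 0.0369% and 0.0430% in the controls.

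A difference in library size was excluded for these low counts, since the mutant libraries had lower totals and still at least 9131 more genes with a count than either control. Genomic DNA in the mutant libraries is a candidate explanation. Over protein-coding genes with no count in either control, the ratio of mutant 2, which is female by Xist, to mutant 1 was 1.53 times as high for 273 X-linked as for 3685 autosomal genes (bootstrap 95% interval 1.33 to 1.77), and 137 Y-linked genes had 175 counts in mutant 1 and 0 in mutant 2. The interval lies below 2, the ratio that DNA alone would give, so part of these counts may have another source. For the 1100 rises at a mean of 5 CPM or more, DNA was excluded as the whole cause for most, since 95.5% were still called after the background was taken off (1051 genes, median background 1.53% of the mutant counts), against 57.4% of the 2042 rises below 5 CPM (1172 genes, median background 12.2%). No biological explanation of the receptor signal was tested.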

How the results depend on the processing

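The removal of background, the limit on it, the mean of at least 5 CPM, robust dispersions and the host gene list tests under each alternative fit were chosen after seeing the data. A fit without 1 mouse library leaves a lone sample that is assumed to vary like the other group. In the mouse 4576 genes passed; 9704 passed with no filter on low counts, 1913 with at least 5 CPM in 2 libraries, 2366 with a mean of at least 5 CPM and 2729 with a fold threshold, where the number of genes tested or the stricter rule sets the count. Leaving out 1 library gave 1260 to 4131. The other settings gave 3066 to 5530, but upper quartile factors, which moved the median of all genes to 0.11, gave 3633 up and 758 down, and DESeq2 1999 up and 2213 down; the cause was not tested. Of 1525 values of named genes under other settings, 1471 kept their direction and side of the threshold, 46 lost the call, 4 gained it and 4 reversed. Of 527 values without 1 library, 424 kept both, 100 lost the call, 1 gained it and 2 reversed. The reversed values lay near 0 and were never called: Ccdc84 (-0.10) went to 0.00926 with upper quartile factors, 0.0158 with at least 5 CPM in 2 libraries and -0.257 to 0.0428 without 1 library, positive without control 2. Rnpc3 (0.05) went to -0.0800 with no filter, -0.0419 with DESeq2 and -0.0272 to 0.0997 without 1 library, negative without control 2.

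Of the 21 lists past the threshold, 0 passed with an estimated correlation, 20 with a replicate block, 19 after background removal and 17 to 20 without 1 library, where 18 to 21 lists passed in all. The direction of the test reversed for unfolded protein response and heat shock genes after background removal (median 0.112) and without control 1 (0.0999; the range without 1 library was -0.0286 to 0.0999). It also reversed for pan-neuronal genes without control 1 (0.0462), control 2 (0.122) or mutant 1 (-0.00172). None of these was called, and the cause was not tested.

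In clbnZM 211 introns passed, 173 to 191 without 1 library and 141 with a replicate block; in clbns846 212 passed, 181 to 189 without 1 library and 172 with a block. The change of the median index was 0.331 in clbnZM, 0.203 as a mean over introns, 0.416 among introns with a mean index of at least 0.05 and 0.317 to 0.340 without 1 library. In clbns846 it was 0.294, 0.166, 0.375 and 0.290 to 0.300. The mean includes introns near 1 in each library and the minimum index leaves out introns near 0. Host gene lists passed in 5 of 20 tests, in 2 on the untransformed index, 0 with a block and 2 to 5 without 1 library; differences between the lines in 0, in 8 on the untransformed index and 0 to 2 without 1 library; the cause was not tested. Of the named introns, 162 of 167 values in clbnZM and 184 of 191 in clbns846 under other settings kept direction and call, and 157 of 168 and 177 of 192 without 1 library; the rest lost the call. A minimum of 2 libraries with a value per group changes nothing, since no value is missing. Comparisons based on U12-type introns in the mouse were not run. With the depth per intron unknown, an index of 0 or 1 cannot be given a limit.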

Other observations

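The families in the next 2 paragraphs were picked after the mouse values were seen, among 10 families computed and 9 tested, and the tests of cell type shares, of the third clbnZM WT library and of other splits were also chosen after the values were seen. Replication-dependent histone genes, whose RNAs are made in S phase and lack a poly(A) tail, fell almost as a block: 57 of 63 were lower in mutants and 0 higher (median log2 fold change -1.25, camera adjusted p = 1e-24; adjusted p = 0.438 with an estimated correlation). Hist1h1b stood at -1.44 ± 0.17 and Hist1h4m at -1.56 ± 0.16 (SE, n = 2), while Hist1h1e, at -0.60, and Hist1h3g, at -0.76, were not called. Members of a histone type are close in sequence, and how reads that map more than once were handled is not given in the sources used here. Whether single members are independent is therefore open.

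Genes of motile cilia, which beat on ependymal and choroid plexus cells, rose in 38 of 52 (0 fell, median 1.74, adjusted p = 2.2e-12; adjusted p = 0.438 with an estimated correlation), and 32 still rose after the background was taken off. Cfap54 was at 2.02 ± 0.21 and the dynein gene Dnah11 at 2.64 ± 0.39. Several members differed between the controls, such as the dynein gene Dnah6 (5.40 and 0.609 CPM), so the amount of plexus in the pieces is not separated from genotype here either. Collagen genes rose in 30 of 45 and fell in 1 (median 1.22, adjusted p = 4.4e-12; adjusted p = 0.0907 with an estimated correlation), with 24 still up after background removal. Ribosomal protein genes had 4 up and 40 down of 237 (median -0.32), solute carriers 72 up and 9 down of 292 (median 0.18), zinc finger genes 19 up and 18 down of 377, small nucleolar RNAs 1 up and 1 down of 49, and clustered protocadherins 0 of 53. Olfactory and vomeronasal receptors that could be tested had 46 of 58 up, and 4 after the background was taken off. The background was measured on receptor genes of these same families, so this drop was fixed in advance and is no evidence for a cause.

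Many markers of cells that Emx1-Cre does not target rose in the mouse mutants. A lower share of the main cell type may raise all such markers alike. Microglia and macrophage genes rose further: their median log2 fold change lay 0.997 above that of endothelium, pericyte and mesenchyme genes (SD of members 0.522, permutation p = 1e-05, the smallest that 100000 draws can give). An equal shift of all such markers predicts no difference between the lists. But the permutation shuffled genes, which moved together in the microglia list (estimated correlation 0.653). Its p therefore does not measure spread between the 2 libraries per group, and a lower share as the whole cause was not excluded. For the other 3 lists a lower share of the main cell type stays open as well. Their medians were 1.04 for endothelium, 1.25 for pericytes and 1.44 for mesenchyme, a span of 0.402 (permutation p = 0.0616). This permutation shuffled genes too, and a p above the threshold does not show equal shifts. It therefore cannot decide whether these lists moved alike. For choroid plexus, Ttr differed 12.1-fold between the controls and the hem gene Lmx1a 1.51-fold, so different amounts of plexus in the dissected pieces and an effect of the genotype cannot be told apart, because 2 libraries per group do not separate dissection from genotype.

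The third WT library of clbnZM had 71.2% of its introns at exactly 0, more than any mutant or other WT library. A mutant library under a WT label was excluded by its values between 0 and 1, which missing reads do not give. Over the 47 such introns where both other WT libraries lay beyond all 3 mutants in either direction, 76.6% were nearer to the WT than to the mutant mean (exact 95% interval 62.0% to 87.7%). The same share, with each library set against the others, was 83.3% and 81.8% in the other WT libraries and 4.94% to 10.2% in the mutants. Fewer reads at its introns may explain the zeros. Of 313 introns at 0.2 or less in both other WT libraries, 11 were at exactly 1 there (3.51%, against 1.29% and 2.56% in the others), and of 98 introns at 1 in both others 60 were at 0 there, against 2 of 42 and 1 of 40 in the others. The share of introns between 0 and 1 was 15.3%, against 50.4% and 50.2%. Reads per intron were not used here, so the depth itself was not measured.

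Loss of minor-intron splicing in one model may show as lower RNA of the same genes in the other. Of 153 zebrafish genes with an intron higher in both lines, 103 share a symbol with a tested mouse gene, and their median log2 fold change in the Rnu11 mutants was -0.26, at percentile 0.04 of 10000 expression-matched random lists (95% from -0.21 to -0.06). The random lists themselves had a median of -0.13. They treat genes as independent, so the percentile does not measure spread between the 2 libraries per group. Of the 103 genes, 28 fell and 4 rose. Eif3i was at -1.12 ± 0.16 and Dctn3 at -0.74 ± 0.11 (SE), both named after their values were seen. The 108 mouse genes that share a symbol with a host of other introns in both tables had a median of -0.15, at percentile 20.8 of their own random lists, with 17 down and 9 up. These sets were not tested against each other. Symbols were matched by spelling alone, so pairs that are not orthologues and orthologues with other names remain.

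Longer introns changed slightly more in both lines, but whether the correlation reaches 0.2 was left undecided. The Spearman correlation of intron length with the change was 0.170 in clbnZM (bootstrap 95% interval 0.0824 to 0.256, permutation p = 0.00012) and 0.176 in clbns846 (0.0885 to 0.261, permutation p = 0.00013), and the bound of 0.2 set before the test lies within both intervals. Median lengths were 319 and 281 bases for introns called higher, against 140.5 and 141.5 for the others. The 6 libraries of a line can be split 3 against 3 in 10 ways. The real split gave 211 introns in clbnZM and 212 in clbns846, the highest other split 1 in each, and with 1 of 10 splits as large the splits are too few for a share under 0.05. For the difference between the lines, all 100 splits drawn gave at least the real count of 0, as any split must, so this says nothing about chance. The highest other gave 4.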
